A study of Mus musculus with 2 samples.

How the data were processed

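RNA of whole uterus from wild-type C57BL/6 mice was extracted with TRIzol as total RNA and made into libraries with a strand-keeping kit (NEBNext Ultra II Directional), per the labels' protocols. One library followed immunoprecipitation with an anti-m6A antibody and the other was the input without antibody. Reads were processed with HISAT2 2.2.1 and MACS3 3.0.0a7 on the mouse build mm10, per the submitters' processing notes. The settings of either tool, the handling of duplicate reads and any filters are not given in the sources used here. The groups were taken from the labels, with 1 library each.

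The only file used was a list of 38366 peaks of the m6A library against the input. The peak list gives, as deposited, start, end and summit in mm10, counted from 0, and they are printed here counted from 1. Its fold enrichment is the ratio of IP pileup to local background at the summit, as the authors' peak caller wrote it. The deposited −log10 p-value and −log10 q-value are those of the caller at the summit, and the lowest −log10 q was 1.32. The deposited display score equals 10 times the −log10 q without its decimals in 99.98% of peaks and was not used further. These scores are the authors' own and serve here to describe, rank and filter peaks within this list. The list carries no strand, so overlapping genes on opposite strands could not be told apart.

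The depth per peak was recovered from the deposited values. The fold was read as (k + 1)/(background + 1) and the p-value as the Poisson chance of more than k fragments, where k is the whole number of IP fragments. A pair of k and background gave the deposited −log10 p within 0.001 at 100% of peaks. Because 1 fragment is added to both terms, the fold understates the enrichment of thinly covered peaks. Above the genome-wide level of 0.462, 69.1% of backgrounds were whole multiples of 0.618, within 0.003 of this step, where 0.6% would be by chance. How many input fragments make 1 step was not established, so no ratio of input to IP depth is given, and the absolute library sizes are not given in the sources used here. PCR copies are not independent molecules, so intervals cover counting error only.

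Gene names and spans came from a RefSeq table of GRCm38.p6, the assembly of mm10. Rows of sequences outside the assembled chromosomes (365) were left out, leaving 49632 genes. No genome sequence, exon, strand or coding positions were used here. The plan linked a peak to a gene by a summit in an exon and matched random lists on spliced length. In their place a summit inside the gene span and the length of that span were used. The planned results on transcript regions, stop codons, DRACH motifs, long internal exons and last exons were not run.

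Gene lists (17) were fixed before the data were examined. Each list count carries an exact Clopper-Pearson 95% interval. Each except that of the long non-coding RNAs also carries a percentile among 10000 random lists matched on gene span in 20 bins. Fisher's exact test compared 5 broadly expressed lists in 10 pairs. The median of the highest fold per gene was compared with random peak-carrying genes by a two-sided permutation test with 100000 resamples, and its interval came from 10000 bootstrap resamples. Adjusted p-values are Benjamini-Hochberg over the pairs or over the lists. In simulated data, 100% of 2000 pileups were recovered. Over 12134 genes and 200 simulated lists of 30 genes, the permutation test called 7.5% of unchanged lists and 89.5% of lists raised 1.4-fold at p under 0.05.

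Genes to be named were fixed beforehand as follows: Pgr, Esr1, Mettl3 and Mettl14; the 12 protein-coding genes with the highest fold at a summit in no other gene and −log10 q of at least 5; the 5 protein-coding genes with the most summits; and in each list the 3 members with the highest fold, with those that have or lack a peak where these are at most 3. Some genes that this rule selects are not reported here. Other genes are named as chosen after their values were seen. Alternatives set beforehand were a −log10 q of at least 5, a fold of at least 4, merging of same intervals, overlap of 1 base or 50% of the peak, leaving out ambiguous summits, the −log10 q as score and matching on length. Added after the data were examined were matching on local background, the median fold per gene, other comparison genes and single-gene summits for the long non-coding RNAs, other bin numbers for the matching and the receptor genes as a comparison set. For the other comparison genes, the new p was adjusted together with the main p of the other lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.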

Results

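The series measured N6-methyladenosine (m6A), a common internal mark of mRNA, across the transcripts of the uterus of wild-type C57BL/6 mice. Methylated RNA immunoprecipitation sequencing (MeRIP-seq) was used: RNA fragments bound by an antibody against m6A are sequenced beside the untreated RNA, called the input. The m6A group held 1 library, labelled as whole uterus of gestation day 4 and gestation day 8 pooled in equal amounts. In the mouse, these days fall near embryo attachment and in the growth of the decidua, the tissue that the uterine stroma forms around the embryo. The input group held 1 library, labelled as whole uterus without antibody, and its label names no pooling. Whether both libraries came from the same RNA is therefore not known. If they did not, a difference in RNA amount between the samples could also give or hide a peak. With 1 library per group there were no replicates, so every value describes this pair of libraries and no test between groups was possible. The 2 days cannot be separated in a pool. All names in the peak list begin with D8posIP-Neginput, which mentions day 8 and does not mention day 4. The makeup of the immunoprecipitated sample therefore rests on its label alone. What Neginput says about the input sample is not known.

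The authors' peak list held 38366 regions enriched in the m6A library over the input. The median peak was 333 bases wide, with quartiles of 225 and 584 bases. Fold enrichment, the authors' ratio of immunoprecipitated (IP) fragments to local background at the peak summit, had a median of 6.16 and quartiles of 4.62 and 8.32. It ranged from 1.47 to 86.05, and 5670 peaks reached at least 10-fold. The depth behind each peak was recovered from the deposited values. The median summit was covered by 29 IP fragments, with quartiles of 15 and 51, against a local background of 3.33 scaled fragments. At 2851 peaks (7.43%) the background was the genome-wide level of 0.462 fragments, so the input gave no local estimate above it. All intervals on fold enrichment below are exact 95% Poisson intervals on the IP fragments with the background held fixed. They cover counting error only, and not variation between animals or libraries.

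**Figure D1:**
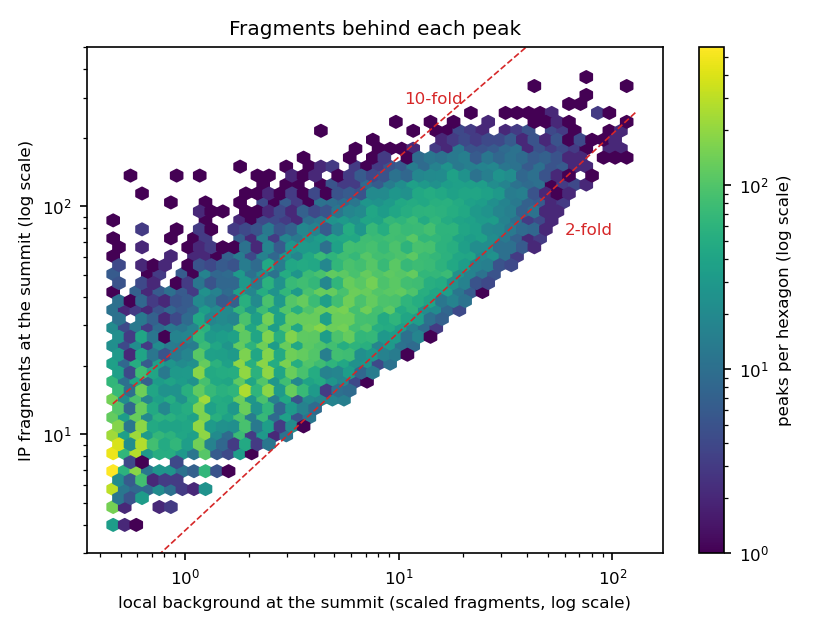
Each hexagon holds peaks with a given local background (horizontal axis, scaled fragments, log scale) and number of IP fragments at the summit (vertical axis, log scale), coloured by the number of peaks on a log scale. Dashed lines mark 2-fold and 10-fold enrichment, and the median peak had 29 IP fragments over a background of 3.33.

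The first question was which transcripts carry m6A peaks in this tissue. Peaks lay mostly in protein-coding genes: 32945 summits (85.9%) fell inside the span of at least 1 such gene, exon or intron. Another 1239 summits (3.23%) fell in long non-coding RNA genes outside protein-coding spans, and 3343 (8.71%) fell outside every annotated gene. A total of 12134 protein-coding genes carried a peak, 55.7% of the 21787 in the annotation, with a median of 2 peaks each. At least 5 peaks were found in 1814 of them and at least 10 in 314. Olfactory and vomeronasal receptor genes, which serve smell and pheromone sensing, were taken as a comparison set. Of these 1455 genes 7 carried a peak, or 0.481% (exact Clopper-Pearson 95% interval 0.194 to 0.989). This set was chosen after the data were examined. Random lists matched on gene span had medians of 170 genes with a peak for the 1105 olfactory and 102 for the 350 vomeronasal genes. Without expression values, the low share may reflect absent transcripts, so it gives no rate of false calls in expressed genes. No exon positions were used here, so a peak in an intron, or in a gene lying inside another, counts toward the span that holds it. A gene without a peak may be unmethylated, unexpressed or too weakly covered, and these cannot be separated without expression values.

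The receptors for the ovarian hormones both carried peaks. Pgr, which encodes the progesterone receptor that pregnancy depends on (NCBI Gene 18667, mm10 chromosome 9, 8898900 to 8968611), held 8 peaks of 3.65-fold to 7.05-fold. The highest spanned 8899863 to 8902066, with its summit 1773 bases from the nearer end of the gene span. A gene end here is either end of the span, where the transcript starts or stops, since no strand was used. Its enrichment was 7.05-fold (5.89 to 8.37), from 128 IP fragments over a background of 17.3. The other 7 peaks ran from 3.65-fold to 5.32-fold. Esr1, which encodes estrogen receptor alpha (NCBI Gene 13982, chromosome 10, 4611989 to 5005633), held 17 peaks of 2.82-fold to 9.96-fold with a median of 3.88. Its highest peak, at 4913072 to 4913560, had 52 IP fragments and 9.96-fold enrichment (7.48 to 13.0). The intervals of the highest peaks in Pgr and Esr1 overlapped.

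**Figure D2:**
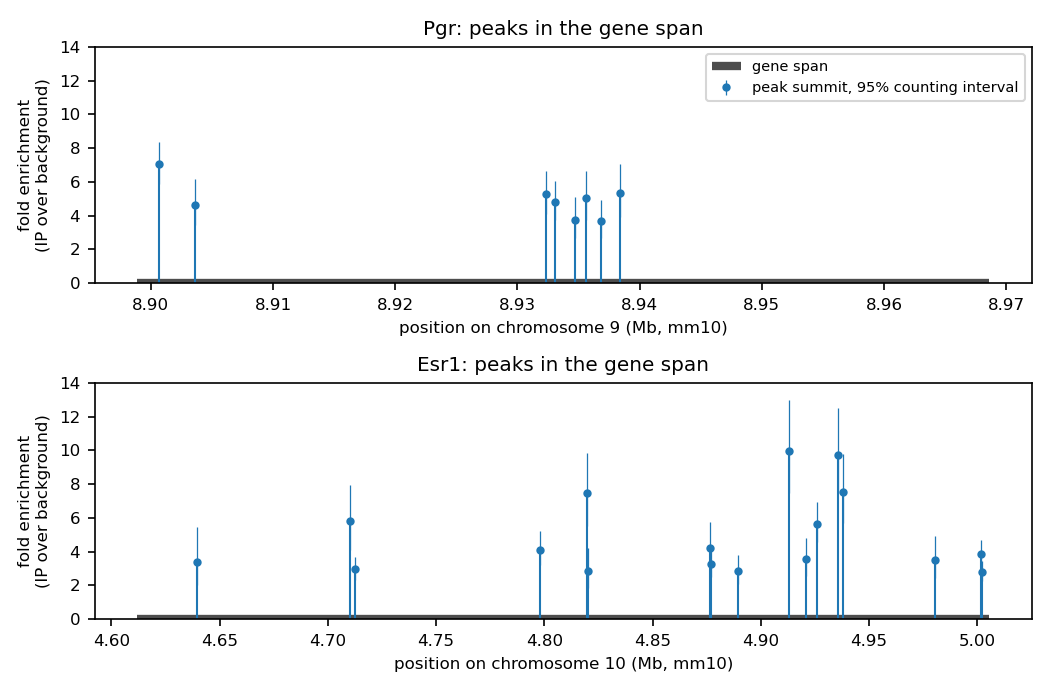
Fold enrichment (vertical axis, IP over background) of each peak summit along Pgr on chromosome 9 and Esr1 on chromosome 10 (horizontal axes, position in Mb, mm10), with exact 95% Poisson intervals for counting error. The grey bar is the gene span: Pgr held 8 peaks up to 7.05-fold and Esr1 held 17 peaks up to 9.96-fold.

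Of the genes for the m6A methyltransferase core, Mettl14 carried a peak and Mettl3 did not. Mettl14, the RNA-binding partner of the enzyme (NCBI Gene 210529, chromosome 3, 123368295 to 123385990), held 1 peak at 123380695 to 123380909. It reached 6.71-fold (3.87 to 10.96) from only 14 IP fragments. Mettl3, the catalytic subunit (NCBI Gene 56335, chromosome 14, 52294841 to 52308741), had no peak in the list. In all, 19 of the 23 genes of the m6A machinery carried a peak. The highest were Zc3h13, a writer-complex subunit, at 23.9-fold (19.1 to 29.6), and the readers Ythdf3 at 21.6-fold (16.7 to 27.5) and Ythdc1 at 20.6-fold (15.5 to 26.9). Besides Mettl3, peaks were lacking in Ythdc2, Igf2bp1 and Elavl1, which were named after their values were seen.

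The most enriched peaks in single protein-coding genes lay in Ahdc1, Znhit6 and Aebp2. Ahdc1, which encodes an AT-hook DNA-binding protein, reached 68.6-fold (57.5 to 81.3) at chromosome 4, 133011432 to 133012266, with 132 IP fragments over a background of 0.939. Znhit6, a factor in small nucleolar RNP assembly, reached 65.2-fold (54.8 to 76.8) at chromosome 3, 145576178 to 145577269. Aebp2, a Polycomb repressive complex partner, reached 55.1-fold (44.95 to 66.8) at chromosome 6, 140623468 to 140624316. The next were Gphn at 54.3-fold, Camk1d at 50.7-fold, Gnai2 at 46.5-fold, Ssbp3 at 46.3-fold, St6galnac3 at 41.6-fold, Syncrip at 41.0-fold, Svbp at 40.8-fold, Peak1 at 40.4-fold and Rp2 at 40.2-fold. Backgrounds at these 12 summits ran from 0.618 in Camk1d, Svbp and Rp2 to 4.32 in Peak1. The median at the highest peak of peak-carrying protein-coding genes was 3.09. These folds rest on little input, and their intervals leave out the error of the background. In 7 of these 12 genes the summit lay within 1000 bases of a gene end, counting either end of the span. The summits in Gphn and St6galnac3 lay 133651 and 100689 bases from one.

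The 5 genes with the most peaks all lay in the clustered protocadherin locus of chromosome 18, which encodes neural cell adhesion proteins. They were Gm37013 with 102 peaks, Gm38666 and Gm38667 with 101 each, Pcdhga1 with 46 and Pcdhga2 with 44. Their spans are nested, and none of these peaks lay in only 1 annotated gene, so the locus is counted repeatedly. Counting only peaks in a single gene, a choice made after the values were seen, put Cpa6 first with 31. Dst, which encodes the cytoskeletal linker dystonin, and Thsd7a followed with 28 each, Tshz2 had 25 and Gpc6 had 24.

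The next question was how peaks were spread over gene groups fixed before the data were examined. Among 28 genes of progesterone signalling, 23 carried a peak (82.1%, exact Clopper-Pearson interval 63.1 to 93.9). The highest were Ptch1, the Hedgehog receptor, at 20.5-fold (13.97 to 29.2), Nr2f2, a stromal nuclear receptor, at 18.0-fold (15.1 to 21.4), and the coactivator Ncoa2 at 16.1-fold (11.7 to 21.7). The Ptch1 peak stood at the genome-wide background of 0.462. Among 26 genes of estrogen signalling, 22 carried a peak (84.6%, 65.1 to 95.6). They include the nuclear receptor corepressors Ncor1 at 15.6-fold and Nrip1 at 12.8-fold. Among 33 genes of decidualization and implantation, 29 carried a peak (87.9%, 71.8 to 96.6). They were led by the secreted signal Wnt6 at 22.5-fold (16.3 to 30.2), the protease inhibitor Timp3 at 20.5-fold (17.0 to 24.5) and the transcription factor Cebpb at 16.8-fold (14.3 to 19.7). The Timp3 summit lay inside 2 gene spans. No peak was listed for Ihh, Areg, Il13ra2, Hsd11b2 and Stat3 of the progesterone list, Lif, Ltf, Fgf1 and Gper1 of the estrogen list, or Ptgs2, Ptgs1, Il11ra1 and Igfbp4 of the decidual list. These 13 genes were named after their values were seen, and they include Lif and Ptgs2, which are needed for implantation in mice.

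Peaks lay in genes listed as markers of the cell types of the uterine wall. In bulk tissue without expression values, a peak in a marker gene does not show which cells held the transcript. All 16 smooth muscle markers, all 16 endothelial markers and all 12 stromal markers had one. In smooth muscle the highest were Lmod1 at 30.3-fold (25.7 to 35.5), Tpm2 at 24.1-fold and Myl9 at 18.4-fold, genes of the contractile apparatus. In endothelium they were the angiopoietin receptor gene Tek at 21.99-fold, Erg at 12.9-fold and the VEGF receptor gene Flt1 at 11.4-fold. In stroma they were Cd34 at 17.5-fold, Pdgfra at 13.4-fold and Twist2 at 11.6-fold. Of 18 epithelial markers 15 had a peak, including Elf3 at 12.6-fold and Wfdc2 at 10.7-fold, while Cldn7, Esrp1 and Grhl2 had none. Of 17 immune markers 13 had a peak, led by the macrophage gene Adgre1 at 16.4-fold and the complement genes C1qb at 11.2-fold and C1qa at 9.76-fold. Cd68, Itgam, Fcer1g and Cd3e, named after their values were seen, had none. Of 21 markers of trophoblast and embryo 10 had a peak, led by the transcription factor genes Tfap2c at 17.5-fold, Eomes at 14.4-fold and Hand1 at 13.0-fold. The Eomes summit lay inside 2 gene spans, and the Eomes and Hand1 peaks rested on 20 and 18 IP fragments. The Adgre1, Eomes and Hand1 peaks stood at the genome-wide background of 0.462. The other 11 markers of trophoblast and embryo had no peak and were named after their values were seen. They were Prl3d1, Prl2c2, Tpbpa, Ascl2, Elf5, Pou5f1, Sox2, Afp, Hbb-y, Hba-x and Hbb-bh1.

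Peaks were also found in most members of the broader lists. They were present in 50 of 51 chromatin regulators (98.0%, 89.6 to 99.95), all but Ezh2, and in 29 of 30 immediate early genes, all but Egr3. They were present in 37 of 38 extracellular matrix genes, all but Fbln1. Of 78 ribosomal protein genes 67 had a peak (85.9%, 76.2 to 92.7), as did 52 of 60 genes of oxidative phosphorylation (86.7%, 75.4 to 94.1). Of 32 proteasome genes 29 had one (90.6%, 74.98 to 98.0), all but Psma1, Psmb2 and Psmb5. Of 14 long non-coding RNAs 12 had one, all but Miat and Mirg, and this count fell to 7 when summits in 2 or more genes were left out. Over the 10 pairs among 5 broadly expressed lists, Fisher's exact test (two-sided, Benjamini-Hochberg) gave 0 differences in share that passed the adjusted threshold of 0.05. The lowest adjusted p was 0.123, and 3 pairs, each with the chromatin regulators, had an unadjusted p under 0.05. With peaks of at least 4-fold, the chromatin regulators exceeded the ribosomal proteins by 35.2 percentage points (Fisher's exact test, adjusted p = 8.73e-06). They exceeded oxidative phosphorylation by 28.0 and the proteasome by 26.2 points, and the m6A machinery stood at -24.1 points to them (Fisher's exact test, adjusted p = 0.000331, 0.00205 and 0.00749). Fisher's test adjusts for neither gene span nor background. Median spans were 78.0 kb in chromatin regulators and 3.17 kb in ribosomal proteins, and median backgrounds at the highest peak were 6.79 and 12.4.

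**Figure D3:**
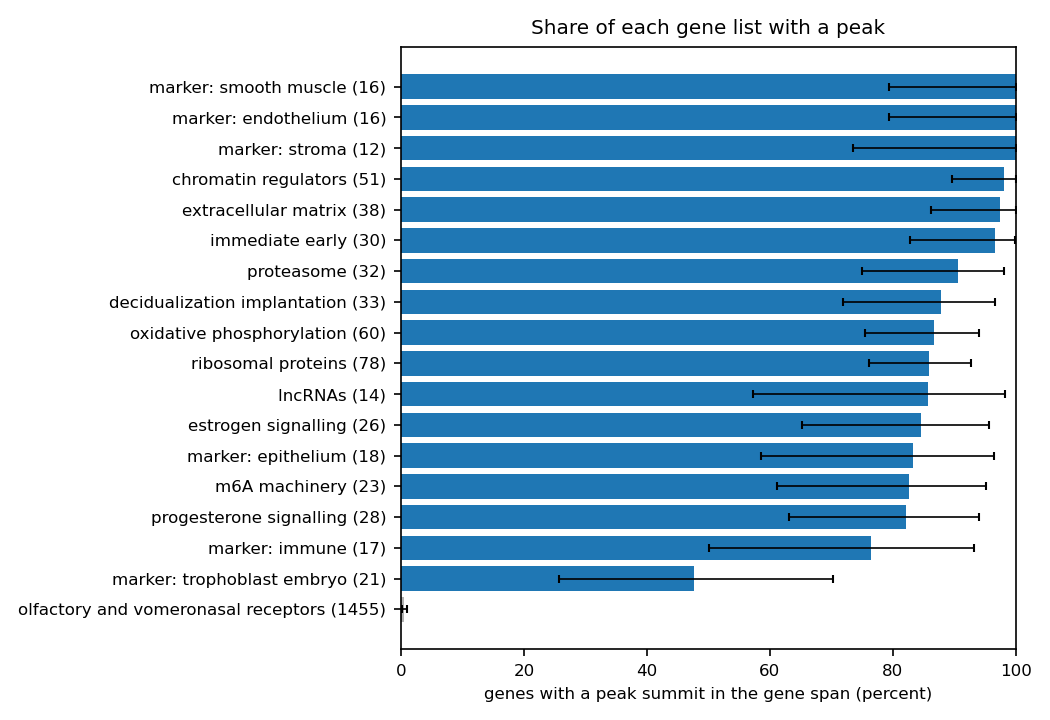
Percent of genes (horizontal axis) with a peak summit in the gene span, for each gene list with its number of members, and for the 1455 receptor genes taken as a comparison set. Error bars are exact Clopper-Pearson 95% intervals. Shares ran from 47.6% for trophoblast and embryo markers to 100% for smooth muscle, endothelial and stromal markers, against 0.481% for the receptor genes.

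Against 10000 random lists of protein-coding genes matched on gene span, the list counts were mostly high. Ribosomal proteins had 67 genes with a peak where random lists had a median of 33, immediate early genes 29 against 14, and decidualization genes 29 against 20. Progesterone genes had 23 against 18 (percentile 98.4), estrogen genes 22 against 17 (percentile 98.9) and the m6A machinery 19 against 15 (percentile 96.6). Markers of trophoblast and embryo had 10 against 10 (percentile 56.7). Random lists include genes that the uterus does not express, so these percentiles do not separate expression from methylation.

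The last question was whether peak-carrying genes of a list were more or less enriched than other peak-carrying genes. Ribosomal protein genes were less enriched: the median of the highest peak per gene was 4.93-fold (95% bootstrap interval 4.57 to 5.62) against 8.04-fold for random peak-carrying genes. Their highest values were 15.3-fold in Rpl24, 10.8-fold in Rpl27 and 10.1-fold in Rps25. Proteasome genes were also lower, at 5.64-fold (4.599 to 6.75), led by Psmd2 at 10.4-fold, Psmc3 at 9.64-fold and Psmd12 at 9.53-fold. The 12 listed long non-coding RNAs with a peak were lower than random protein-coding genes as well, at 5.08-fold (3.17 to 6.52). They were led by the imprinted Airn at 12.2-fold and Meg3 at 10.7-fold, and by Kcnq1ot1 at 7.18-fold. Kcnq1ot1 is 1 of 5 members whose summits all lay in more than 1 gene. Over all peaks, the median was 6.16-fold in long non-coding RNA genes outside protein-coding spans and 6.09-fold in protein-coding genes. Chromatin regulators were higher, at 9.96-fold (9.19 to 10.8), led by Bptf at 35.7-fold (29.7 to 42.6), Chd7 at 32.2-fold and Hcfc1 at 29.1-fold, which act in remodelling or transcriptional control. The Chd7 peak stood at the genome-wide background of 0.462. Chromatin regulators had a median of 6 peaks per gene, against 2 over all peak-carrying protein-coding genes. The highest of more peaks tends to be higher, and the number of peaks was not matched. In a two-sided permutation test of each list's median, with Benjamini-Hochberg adjustment over 17 lists, the log2 ratio to random genes was -0.71 for ribosomal proteins (adjusted p = 0.00034, the smallest the permutations can give). In the same permutation test it was -0.51 for the proteasome (adjusted p = 0.0109), -0.66 for long non-coding RNAs (adjusted p = 0.0275) and 0.31 for chromatin regulators (adjusted p = 0.0275). Genes are the units of this permutation test, so it describes this peak list and not variation between animals.

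None of these 4 differences held under every setting. Local background at the highest peak was 12.4 in ribosomal proteins, 7.41 in the proteasome, 15.1 in long non-coding RNAs and 6.79 in chromatin regulators, against 3.09 over all peak-carrying protein-coding genes. This background is the denominator of the fold, so matching on it compares mainly IP fragments. Against random genes matched on that background, a setting added after the data were examined, the log2 ratios of the 3 lower lists were -0.26, -0.31 and -0.077 (permutation test, adjusted p = 0.0794, 0.118 and 0.808), while the chromatin ratio was 0.44 (adjusted p = 0.00034). With −log10 q as score, the ribosomal and long non-coding ratios reversed to 0.21 and 0.54 and the proteasome stood at -0.45 (permutation test, adjusted p = 0.397, 0.292 and 0.289). With a fold of at least 4, the proteasome and long non-coding calls ended, at -0.42 and -0.51 (permutation test, adjusted p = 0.0704 and 0.196). The proteasome call also ended with the median over a gene's peaks, at -0.20 (permutation test, adjusted p = 0.151). Against random long non-coding RNA genes with a peak, a comparison added after the data were examined, the long non-coding ratio was -0.46 (permutation test, adjusted p = 0.0840). With only summits in a single gene, 7 members remained, and the ratio was -0.81 to protein-coding and -0.59 to long non-coding genes (permutation test, adjusted p = 0.0458 and 0.0399). The chromatin call ended with a −log10 q of at least 5, a fold of at least 4 or matching on gene span, at 0.28, 0.25 and 0.24 (permutation test, adjusted p = 0.0579, 0.119 and 0.103), and its ratio was -0.015 (adjusted p = 0.933) with the median over a gene's peaks in place of the highest.

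The other 13 lists did not pass the permutation test, with adjusted p from 0.173 to 0.942. The medians were 8.26-fold for progesterone genes, 8.64-fold for estrogen genes, 8.48-fold for decidualization genes and 8.66-fold for immediate early genes, led by Klf2 at 23.8-fold, Nfkbia at 20.4-fold and Egr2 at 13.8-fold. Oxidative phosphorylation stood at 8.08-fold, led by Ndufa12 at 28.8-fold, Ndufs5 at 25.4-fold and Ndufa8 at 20.1-fold. Extracellular matrix genes stood at 6.78-fold, led by the collagen genes Col14a1 at 21.0-fold, Col6a3 at 14.6-fold and Col4a1 at 14.4-fold. The m6A machinery had a median of 10.2-fold. Among cell type markers the medians were 10.8-fold for trophoblast and embryo, 10.5-fold for smooth muscle, 8.12-fold for stroma, 8.08-fold for endothelium, 7.65-fold for epithelium and 6.16-fold for immune cells.

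**Figure D4:**
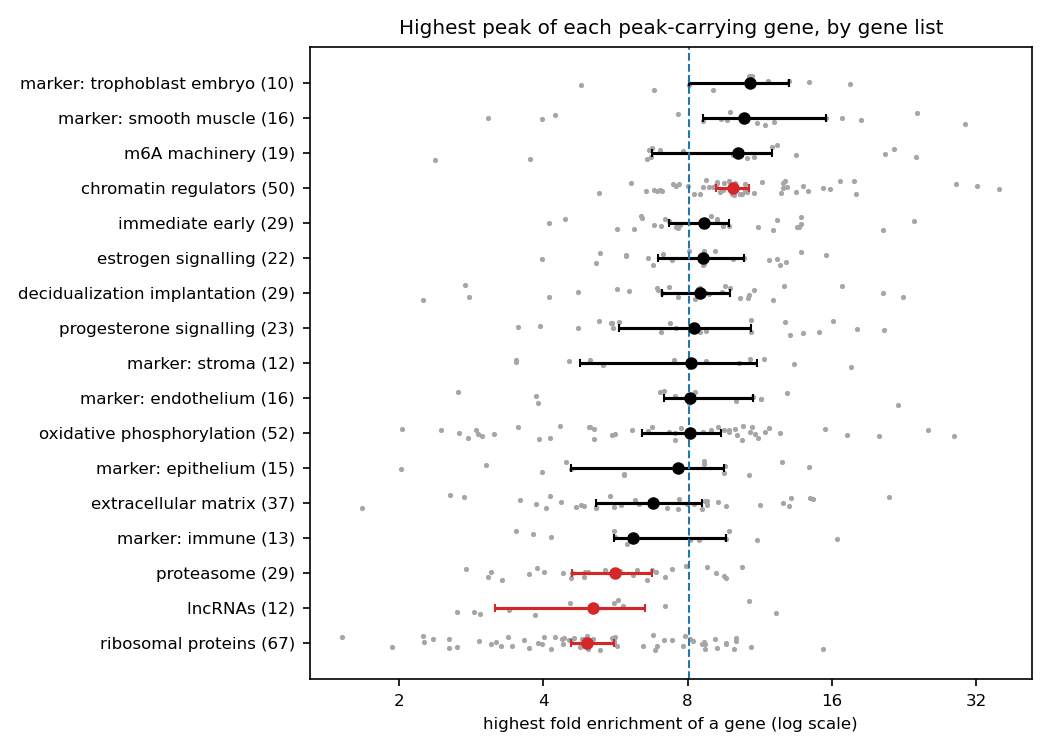
Highest fold enrichment per peak-carrying gene (horizontal axis, log scale) for each gene list, with the number of such genes; grey points are genes, large points are medians with 95% bootstrap intervals, red where the adjusted permutation p was under 0.05. The dashed line is the median of 8.04 over all peak-carrying protein-coding genes, and ribosomal proteins had the lowest median at 4.93.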

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

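The tests on the Y chromosome, gene ends and local background, and those with other bin numbers, were chosen after the data were examined, while matching on length was set beforehand. Peaks looked at further were the 3343 beyond every gene span, the 62 on the Y chromosome and the 10 on the mitochondrial chromosome. Only peaks beyond every gene span lay outside the gene-based comparisons. Some Y peaks, such as the highest, are among them. The 3343 peaks outside genes had a median fold of 6.16 from 12 IP fragments, and 31.1% of them stood at the genome-wide background. Of these, 41.0% lay within 5000 bases of a gene. They include 7 of the 20 highest peaks of the list. In the mitochondrial chromosome 9 of 10 peaks were under 4-fold, and the other, in mt-Rnr1, reached 8.27-fold from 256 IP fragments.

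The highest peak of the whole list lay on the Y chromosome at 90819081 to 90821263, at 86.05-fold (72.2 to 102, counting error only), with 135 IP fragments over a background of 0.581. RNA from male embryos is a candidate source, as is RNA of X-linked sequence that has a copy on the Y chromosome. Of 4 broadly expressed Y-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty, only 1, Ddx3y, had a peak, with 7 IP fragments, while 3 of their 4 X-linked partners had one, which is too few to decide on male RNA. A cluster of 33 of the 62 Y peaks (53.2%) lay from position 90721916 onward, near the end shared with the X chromosome, and 29 lay before it. No sequences were compared, so neither source is excluded, and no biological explanation was tested.

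Ribosomal protein and proteasome genes had lower highest peaks than random peak-carrying genes, by -0.71 and -0.51 on the log2 scale. Short gene spans are argued against as the whole cause, since both lists stayed lower against genes matched on span. The unadjusted permutation p was 2e-05, the smallest possible, and 0.00638. Both lists also stayed lower in all 40 runs with other bins and tie orders. Numbers of peaks per gene were not matched, and their medians were 2 and 1, against 2 over peak-carrying protein-coding genes. With the median over a gene's peaks, also chosen after the data were examined, the log2 ratios were -0.45 and -0.20 (permutation test, adjusted p = 0.00034 and 0.151). Few peaks per gene therefore stay open as a cause, above all for the proteasome. Transcript abundance was not measured. Local background is the denominator of the fold and was taken at each gene's highest peak. Matching on it therefore cannot show how much of either difference background causes. Such matching moved the log2 ratios to -0.26 and -0.31. The unadjusted permutation p was then 0.0144 and 0.0417, but 4 bin numbers from 20 to 200 with 10 orders of tied genes gave 0.0116 to 0.0505 and 0.0152 to 0.0862. The threshold of 0.05 was met in 39 of 40 and 35 of 40 runs, and not after adjustment over the lists. Whether background is part or the whole of the cause therefore remains open, and no biological explanation was tested.

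Peaks within 250 bases of either end of a gene span were more enriched than peaks farther inside, with a median of 6.63-fold. The log2 difference was 0.13 over 25789 peaks in genes above 10000 bases. Peaks were also more frequent near the ends. Within 250 bases lay 7.36% of them and at 250 to 500 bases 5.06%, against 1.36% each if spread evenly along the spans. Beyond 5000 bases lay 51.7%, against 72.8%. Even spread takes no account of introns or of transcript coverage. Enrichment did not rise steadily toward the ends. Medians were 5.65-fold at 250 to 500 bases, 5.74-fold at 500 to 1000 and 5.87-fold at 1000 to 2000. They were 6.16-fold at 2000 to 5000 bases and also beyond 5000. Background, the denominator of the fold, was lower too within 250 bases, at 2.11, which could produce the difference. Within 20 strata of background the log2 difference was 0.05 (one-sided permutation p = 0.0140). With 50, 100 and 200 strata, tried after that result was seen, the permutation p was 0.217, 0.244 and 0.0830. Background therefore stays open as the whole cause of the fold difference, and no biological explanation was tested.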

How the results depend on the processing

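Alternatives on the local background, the median fold per gene, the comparison genes of the long non-coding RNAs and the number of bins were added after the data were examined; the others were set beforehand. The peak count ran from 32394 to 38366 and the count of protein-coding genes with a peak from 11141 to 12227, within 1.5 times the main counts; no intervals were repeated. List counts also stayed within 1.5 times, except for the long non-coding RNAs, with 7 in place of 12 at a fold of at least 4 and 7 without ambiguous summits. Of 105 alternative values of the fold tests, 67 kept their direction and their side of the threshold. For the rest, given as log2 ratios with adjusted permutation p, the cause was not tested. Chromatin regulators were at 0.28 (0.0579) with −log10 q of at least 5, 0.25 (0.119) with a fold of at least 4, 0.24 (0.103) matched on gene span, and reversed at -0.015 (0.933) with the median fold per gene. The proteasome was at -0.42 (0.0704) with a fold of at least 4, -0.45 (0.289) with −log10 q as score, -0.31 (0.118) matched on background and -0.20 (0.151) with the median fold. Ribosomal proteins reversed to 0.21 (0.397) with −log10 q as score and were at -0.26 (0.0794) matched on background. Long non-coding RNAs were at -0.51 (0.196) with a fold of at least 4, -0.077 (0.808) matched on background and -0.46 (0.0840) against random long non-coding RNA genes, and reversed to 0.54 (0.292) with −log10 q as score. That score, which grows with depth, brought decidualization genes to 0.70 (0.0392), immediate early genes to 1.03 (0.000907), endothelium to 0.88 (0.0392), smooth muscle to 1.32 (0.00068) and progesterone genes to 1.05 (0.00153). Smooth muscle reached 0.53 (0.0450) matched on background. With the median fold, extracellular matrix genes reached -0.42 (0.00034) and oxidative phosphorylation reversed from 0.0086 to -0.20 (0.0382). Ratios that passed in neither setting also changed sign. With −log10 q of at least 5 these were endothelium (-0.020), epithelium (0.076), stroma (-0.023) and oxidative phosphorylation (-0.022). With a fold of at least 4 they were endothelium (-0.018) and epithelium (0.047), and matched on gene span endothelium (-0.019) and epithelium (0.029). Matched on background, epithelium was at 0.045. With −log10 q as score, estrogen genes were at -0.0014, extracellular matrix genes at 0.49 and immune markers at 0.13. With the median fold, decidualization genes were at -0.22, stroma at -0.35 and progesterone genes at -0.14, while immune markers were at exactly 0, with no direction, against -0.39 in the main setting. In 8 cases a pair of lists passed Fisher's test where the main setting did not. Differences in share, in percentage points, changed sign without passing in 7 cases. With −log10 q of at least 5, oxidative phosphorylation minus ribosomal proteins was -0.385, and the m6A machinery was 0.557 above ribosomal proteins and 0.942 above oxidative phosphorylation. With a fold of at least 4 the m6A machinery was 11.1 above ribosomal proteins, 3.91 above oxidative phosphorylation and 2.04 above the proteasome. Without ambiguous summits, the proteasome minus oxidative phosphorylation was -0.625. No paired analysis was possible because each group held 1 library, and no library could be left out. The results on transcript regions, stop codons, motifs, long internal exons and last exons, with their alternatives, were not run.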

Other observations

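Families of genes were grouped by symbol after the data were examined, and all tests in this part were chosen then. There were 13 families looked at in all, of which histones matched no symbol in the search used. Zinc finger genes named Zfp, many of them transcriptional repressors, had the highest share of these families: 359 of 397 carried a peak (90.4%, exact Clopper-Pearson interval 87.1 to 93.1). The highest were Zfp651 at 24.95-fold, Zfp462 at 23.3-fold and Zfp282 at 23.3-fold. Homeobox genes of the Hox clusters, which set position along the body, carried peaks in 22 of 39 cases, against a median of 19 in random lists matched on gene span, including Hoxa10 at 4.72-fold and Hoxa11 at 8.26-fold, both required for implantation. Of 19 Sox genes 12 had a peak, against 10 in such random lists, and of 44 forkhead genes 21, against 23. Of 389 solute carrier genes 219 had one, against 247 (percentile 0.15 of those lists). Of 19 Wnt genes 8 had one, against 12 (percentile 4.01), among them Wnt6 at 22.5-fold, Wnt5b at 15.8-fold, Wnt5a at 12.4-fold and Wnt4 at 10.3-fold.

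Other families had fewer members with a peak than random lists matched on gene span, whose medians follow. No expression values were used, so members that are not expressed cannot be set apart. Of 26 prolactin family genes 3 had one, against 14: Prl3c1 at 8.29-fold, Prl8a2, the decidual prolactin-related gene, at 4.72-fold from 170 IP fragments, and Prl8a9 at 3.58-fold. Of 49 keratin genes 8 had a peak, against 25, among them the simple epithelial keratins Krt18 at 7.65-fold, Krt19 at 5.90-fold, Krt7 at 4.46-fold and Krt8 at 3.98-fold. Of 22 fibroblast growth factor genes 6 had one, against 13, led by Fgf18 at 12.3-fold, Fgf2 at 11.9-fold and Fgf7 at 11.1-fold. Of 92 cytochrome P450 genes 16 had one, against 55, including Cyp11a1, which starts steroid synthesis, at 7.02-fold from 71 IP fragments. Olfactory receptors had 5 of 1105, against 170, and vomeronasal receptors 2 of 350, against 102.

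The zinc finger count prompts the hypothesis that these transcripts may be methylated more often than most. Long gene spans are argued against as the whole cause, since random lists matched on span gave a median of 241 genes with a peak (95% of lists from 223 to 260) against the observed 359. Broad expression of the family was not tested and stays open, as do shared reads between similar zinc finger genes. A count above that of random lists is not particular to this family, since ribosomal proteins had 67 against 33 and chromatin regulators 50 against 37. The hypothesis was found on these data and was not tested. A comparison with other genes of equal expression in the input would be needed to decide it.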
